A study of Mus musculus with 12 samples.

How the data were processed

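Gene expression was measured in dorsal root ganglia of 15-day-old mice with single-colour Illumina mouse BeadChips. Per the labels, each array carried total RNA from a pool of ganglia of lumbar levels 3 to 6, and all mice came from a mixed C57/BL6 and 129Ola background. There were 12 arrays: 6 of control pools and 6 of pools from conditional mutants in which Isl1-driven Cre recombinase targets the Maf gene. Group and replicate number were read from the sample titles. The labels do not state how many mice made a pool, so the p-values below measure the spread between pools. The array identifiers in the labels place replicates 1 to 3 of both groups on one BeadChip and replicates 4 to 6 of both groups on another.

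The deposited intensity of each probe is the bead summary that GenomeStudio gave, per the submitters' processing notes, with the version not given. These deposited intensity values were not subtracted for background and not normalized between arrays: the lowest value of an array lay between 42.4 and 45.8 and the median between 86.1 and 99.6. The file headers name a column of detection p-values for each array. The detection p-value of a probe was taken to set its intensity against the negative controls of the same array. A further deposited table holds processed intensity values of the same 12 arrays on a linear scale. How it was made is not given in the sources used here. Its values reached down to -25.1, its column medians lay between 24.1 and 24.2, and each column ranked the probes exactly as the matching array did (Spearman correlation 1 on each of the 12 arrays), so it was treated as background-subtracted and normalized between arrays, and it was used as an alternative alone. No 2 arrays held identical values, and correlations between arrays ran from 0.976 to 0.992.

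From the intensity table, log2 values were computed with neqc in limma 3.58.1 under R 4.3.3. This step estimates the background from the detection p-values, applies the normexp correction with an offset of 16 and makes the distributions of all arrays equal by quantile normalization. Probes were kept when detected at p under 0.05 on at least 6 of the 12 arrays, which left 13177 of 25697 probes and removed 12520. Gene symbols came from the platform annotation: 23978 probes had 1 symbol, 0 had several and 1719 were not listed. Of these, 23962 were matched by gene identifier to RefSeq names for assembly GRCm38.p6, and 0 symbols changed. Among the tested probes, 772 carried no gene name here. A gene was represented by its detected probe with the highest mean over all 12 arrays, which gave 9223 genes. The RefSeq table was used for names and for the order of genes along chromosomes only. On each array between 12822 and 13491 probes were detected, and the number of arrays limits the precision.

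Mutant and control pools were compared probe by probe with limma (lmFit and eBayes) on genotype alone, and probes with a Benjamini-Hochberg adjusted p under 0.05 were called. Changes are log2 differences, mutant minus control, with their standard errors. Where no array of a group detected a probe, the fold is given as a lower bound: the mean of the brighter group over all its arrays, set against a floor for the dimmer group. The floor of an array was the higher of its lowest signal among detected probes and the probe's own value, and floors were averaged over the arrays of the group.

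A total of 40 gene lists covering sensory neuron types, ion channels and receptors, glia, other cell types of the ganglion and its surroundings, and general cell functions were fixed in advance. Of these, 37 had at least 4 tested members. The lists of ion channels, receptors, ribosomal proteins and some others were filled by symbol prefix. A few members are thus not of the named class, among them Rps6ka3, Rps6ka5, Rps6kl1 and Rps19bp1 in the ribosomal list and Scnm1 in the sodium channel list. Each list was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with camera's estimated correlation and with fry. Adjustment over the members of a list alone is given beside that over all tested probes. A score for a list on an array is the mean over its members of the log2 value minus the member's mean over the 12 arrays, and differences of scores were tested by exact two-sided permutation of the 12 arrays.

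The genes to be named were also set by rule: a few genes whatever their result, Maf, Mafa, Ret and Isl1 among them, the 12 genes that rose most and the 12 that fell most, up to 4 called members of each list, the 5 genes with the smallest p in a direction with fewer than 10 calls, the neighbours of Maf and Isl1 in chromosome order, and the most abundant detected member of each list of tissues that could be carried along. The grouping, the test, the lists, this rule and most alternatives were chosen before the data were examined; the few added later are named where their results are given.

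The steps were tested on simulated arrays made for the comparison of mutant with control from the real means and standard deviations of 9223 genes, with 200 changed genes in each of 10 runs. Changes of 0.5, 1 and 2 on the log2 scale were called for 68.5%, 96.7% and 100% of the changed genes, and 4.80% of all calls were unchanged genes. The real arrays gave 25 called genes, so their cutoff was stricter and small changes would be called less often there. Genes varied independently in these runs, so the share of 4.80% need not hold for the real pools. A list of Schwann cell genes moved by -0.25 was called in 10 of 10 runs, and in 0 of 10 runs without the shift; members varied independently in these runs, unlike in the real pools. Over all lists there was 1 call in the 10 runs without the shift.

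The alternatives covered other background corrections and normalizations, the processed table, the filter on dim probes, the chip as a block and each chip alone, the replicate number as a block, array weights, a trended and robust variance prior, the mean of a gene's probes, other thresholds, other set tests and leaving out each array. Single pools far from the rest of their group were sought with Dixon's criterion over named genes and list scores. The count of genes was also set against that of other splits of the 12 arrays into 6 and 6. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.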

Results

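Total RNA of dorsal root ganglia, which hold the cell bodies of the somatosensory neurons, was profiled at 15 days of age in 6 control pools and 6 Maf conditional mutant pools. Maf encodes a basic leucine zipper transcription factor, also called c-Maf, and the Cre line used acts in cells that express the sensory neuron transcription factor Isl1. The comparison asks which transcripts of the whole ganglion differ between these mutant and control pools. Detected probes numbered 12822 to 13491 per array.

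The targeted gene was read first. Maf (Entrez Gene 17132, chromosome 8) was detected in 6 of 6 control pools, at a log2 level of 7.44 ± 0.29 (SD, n = 6), and in 0 of 6 mutant pools, whose values averaged 4.57 ± 0.08 (SD, n = 6). The fitted log2 change, which depends on the background value, was -2.87 (SE 0.12, limma adjusted p = 6.3e-09). Because no mutant array detected the probe, the reduction is bounded as at least 4.48-fold. The position of the single Maf probe relative to the removed part of the gene is not known here.

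Expression of a small set of genes was lower in mutant ganglia. Cryba2, a beta-crystallin of the lens, fell by 2.38 on the log2 scale. Hapln1, a link protein that joins hyaluronan and proteoglycans, fell by 1.37. Kcng4, a modulatory potassium channel subunit, was detected in no mutant pool. Myh8, the perinatal myosin heavy chain, fell by 1.25, and Calb2, the calcium-binding protein calretinin, fell by 1.06. In all, 31 of 13177 probes passed the threshold, 28 of them lower and 3 higher in mutants. Counted by the brightest probe, these were 25 of 9223 genes, of which 23 were lower and 2 higher. In each of the 23 lower genes all 6 mutant pools lay below all 6 control pools, and in both higher genes all 6 lay above. The calls rest on these same values, so the separation of called genes is no separate evidence. Over all tested genes, 56 were separated in the lower direction and 11 in the higher direction, where chance gives 0.108% of genes, or 9.98, in each direction. At an unadjusted p under 0.05 there were 835 probes, 497 lower and 338 higher, with 659 to be expected by chance. The median SE of a change was 0.10.

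**Figure D1:**
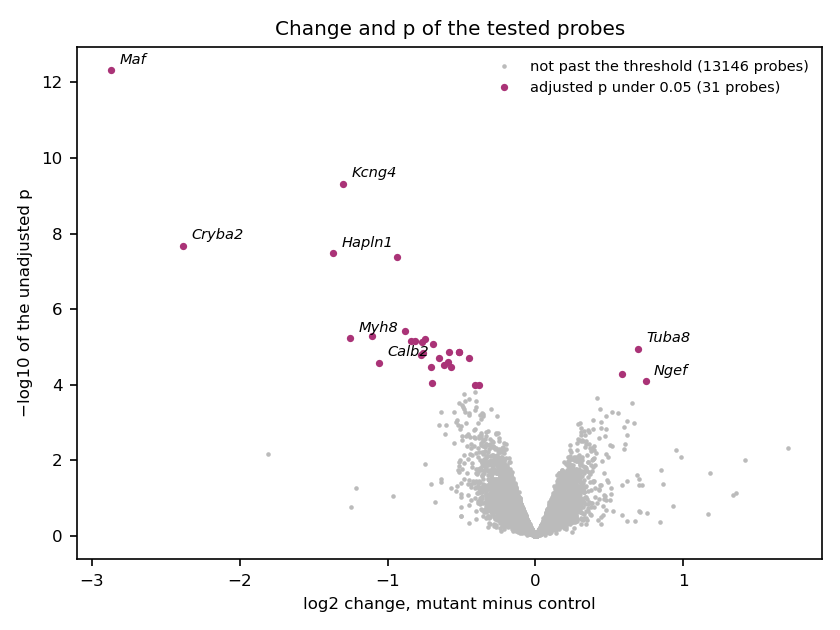
Change and p of the tested probes. The horizontal axis is the log2 change, mutant minus control, the vertical axis is −log10 of the unadjusted p from limma, and each point is 1 probe; the 31 probes past the threshold are coloured, 28 to the left of 0 and 3 to the right, with Maf farthest to the left at -2.87.

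Cryba2 went from 9.26 ± 0.55 in controls to 6.88 ± 0.25 in mutants (SD, n = 6 each, limma adjusted p = 9.2e-05). Hapln1 went from 7.29 ± 0.32 to 5.92 ± 0.11 (adjusted p = 0.00011). Kcng4 was detected in 6 of 6 control pools and 0 of 6 mutant pools, a reduction of at least 1.76-fold (adjusted p = 3.1e-06). It lies on chromosome 8 near Maf. With Kcng4 and the nearby gene Vat1l left out, 6 of the 40 tested genes nearest to Maf had an unadjusted p under 0.05. Windows of that size along the genome had a median of 2 and a 95th percentile of 6. Calb2, also on chromosome 8, went from 9.77 ± 0.34 to 8.71 ± 0.34 (adjusted p = 0.015), and its dimmer probe fell by 1.11. The call of the brighter Calb2 probe was lost without control replicate 6 or without mutant replicate 1, each with an adjusted p of 0.052. Lgi2, a secreted leucine-rich repeat protein, fell by 0.94 (SE 0.09, adjusted p = 0.00011). Slc35d3, a member of the nucleotide sugar transporter family, fell by 0.84, Prokr1, a receptor for prokineticins, by 0.82, and Insyn2b by 0.77. Ntng1, the membrane-anchored adhesion protein netrin-G1, fell by 0.76, and Rgs6, a regulator of G protein signalling, by 0.75. The sizes for Hapln1 (-0.88), Slc35d3 (-0.46) and Rgs6 (-0.44) were smaller with normexp at offset 50, where they stayed past the threshold. In the reported fit the adjusted p-values of Slc35d3, Prokr1, Insyn2b, Ntng1 and Rgs6 lay between 0.00801 and 0.0113. Both tested probes passed for Prokr1, Calb2 and Myh8, while the second Ntng1 probe stood at -0.61 with an adjusted p of 0.21.

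Of the 23 lower genes, 14 are named by the rule and 9 lie outside it, the latter listed here after their values were seen. The 9 are Glb1l2, Vstm2b, Ccdc172, Clmp, Tmem108, Omg, Cpne6, H4c12 and Sphk1, and they fell by 0.38 (Sphk1, sphingosine kinase 1) to 0.70 (Glb1l2). With the replicate number as a block 3 of these 9, Ccdc172, Clmp and Tmem108, kept a call and 6 did not. Omg, the oligodendrocyte myelin glycoprotein, fell by 0.52. Among the 28 lower probes 1 carries no gene name here. For 2 genes a dimmer probe passed while the brightest did not. A dimmer probe of Medag passed at -0.88 while its brighter probe stood at -0.50 with an adjusted p of 0.22. A dim probe of Elmo1, the third higher probe, passed at 0.58 while the brightest of its 6 tested probes stood at -0.04 with an adjusted p of 0.97. The other Elmo1 probes stood at -0.48, -0.55, -0.36 and -0.06, none past the threshold.

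The 2 higher genes were Tuba8, an alpha-tubulin, and Ngef, a guanine nucleotide exchange factor known as ephexin. Tuba8 rose from 6.59 ± 0.14 to 7.28 ± 0.23 (SD, n = 6 each), a change of 0.70 (SE 0.11, adjusted p = 0.010). Ngef was detected in 0 of 6 control pools and in 6 of 6 mutant pools, which makes it at least 1.28-fold higher (log2 change 0.74, adjusted p = 0.037). The Ngef call was lost in 16 of the 25 alternatives that tested it, and its adjusted p over all 25 ran from 0.015 to 0.60. Leaving out any 1 of control replicates 1, 4, 5 and 6 and mutant replicates 1, 2, 3 and 6 ended it, with adjusted p from 0.066 to 0.12. Next by p, and not past the threshold, were Apobec1 (0.42, adjusted p = 0.085), Wnt7a (0.65, adjusted p = 0.10), Caln1 (0.44, adjusted p = 0.13), Lyz2 (0.56, adjusted p = 0.14) and Rasgrf1 (0.48, adjusted p = 0.15).

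**Figure D2:**
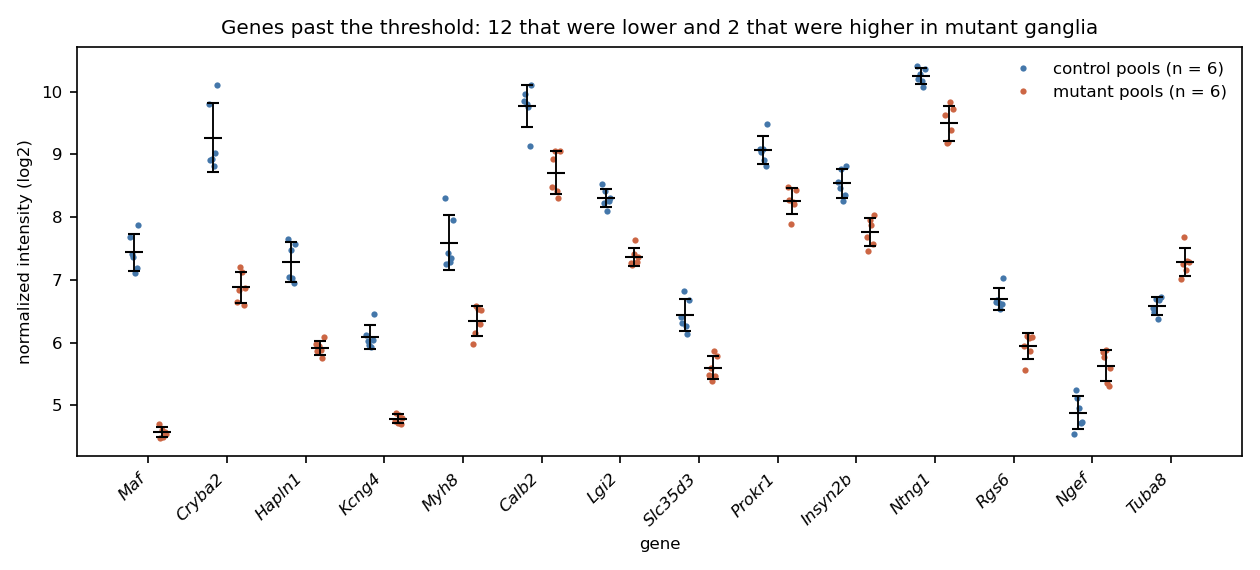
Normalized log2 intensity (vertical axis) of 12 lower and 2 higher genes (horizontal axis) in each pool. Points are pools, with 6 control and 6 mutant pools per gene, bars are the mean ± SD, and for each of these genes the 6 mutant values lie apart from the 6 control values; Maf, for example, averaged 7.44 in controls and 4.57 in mutants.

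Each chip held 3 control and 3 mutant pools. With the chip as a block 23 genes passed, all 23 of them among the 25. Within chip 1 alone 4 genes passed and within chip 2 alone 1 passed, each from 3 pools against 3. All 25 genes had the same direction on both chips. This follows from the separation of all mutant from all control pools and is no separate evidence. Sizes were at least 0.48 on the first chip and 0.28 on the second. A limma test of the product of genotype and chip called 0 of 13177 probes, with 372 at an unadjusted p under 0.05, where chance gives 659. Mutant replicate 3 lay apart from the other 11 arrays, and without it 21 genes passed, all 21 of them among the 25.

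The lens crystallin list was lower in mutants. All 5 of its tested members were lower, with a mean change of -0.71 (camera adjusted p = 3.9e-07, and adjusted p = 0.0084 with an estimated correlation). It was the 1 list of 37 that passed with the preset correlation, the estimated correlation and fry alike. Cryba2 was the 1 member past the threshold over all probes, and 3 of 5 passed adjusted over the list alone: Cryba2, Crybb1 (-0.51) and Crybb3 (-0.28). Cryba4 (-0.17) and Cryab (-0.22) did not pass. Crybb1 was detected in 1 of 6 mutant pools and Crybb3 in 2 of 6, so that the sizes of these 2 changes depend on values near background. The mean change was -0.74 within chip 1 and -0.68 within chip 2.

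Low-threshold mechanoreceptors are the neurons that sense touch and vibration. In the list of rapidly adapting and A-beta field mechanoreceptors 2 of 14 members fell, Calb2 and Ntng1, and 3 passed adjusted over the list alone, Nefh (-0.30), the heavy neurofilament, being the third. The receptor tyrosine kinase Ret, a marker of the early rapidly adapting lineage, stood at 10.87 ± 0.12 in controls and 10.75 ± 0.13 in mutants (SD, n = 6 each), a change of -0.12 (adjusted p = 0.89). Its co-receptor Gfra1 stood at -0.03 and the transcription factor Shox2 at -0.43, neither past the threshold. The list as a whole, with a mean of -0.12, was not called (camera adjusted p = 0.21). The A-delta D-hair list (6 members, mean 0.08, adjusted p = 0.25) and the C-fibre low-threshold list (6 members, mean 0.05, adjusted p = 0.52) held 0 called genes. Piezo2, the transduction channel of touch, stood at 0.05.

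Among proprioceptor markers Insyn2b was the 1 of 8 that fell, while Whrn (0.31) was higher adjusted over the list alone. Pvalb (0.07), Etv1 (-0.14) and Ntrk3 (-0.03) did not pass, and neither did the list (mean -0.09, adjusted p = 0.79). Of the 16 genes of large-diameter and neurofilament-rich neurons 0 passed over all probes and 5 passed adjusted over the list alone: Nefh (-0.30) and Kcna1 (-0.52) lower, Ina (0.60), Kcnc1 (0.32) and Scn4b (0.25) higher. That list was not called (mean -0.06, adjusted p = 0.46). The list of sensory neuron transcription factors (19 members, mean -0.06, adjusted p = 0.46) held no called gene, and Isl1 itself stood at -0.30 (SE 0.13, adjusted p = 0.77).

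Peptidergic nociceptor genes were higher as a list, with 6 of 8 members above 0 and 0 past the threshold alone. The mean was 0.12 (camera adjusted p = 0.045), and adjusted p = 0.43 with an estimated correlation. Adcyap1 (0.29) and Tac1 (0.25), which encode the neuropeptides PACAP and substance P, moved farthest. The call was lost without any 1 of control replicates 2, 3, 5 and 6 and mutant replicates 1, 2, 4 and 5, with adjusted p from 0.061 to 0.25. It was also lost in camera with array weights (adjusted p = 0.092) and with the processed table (adjusted p = 0.053). With pools permuted rather than genes, the list score had an exact permutation p of 0.063 (adjusted p = 0.126 over 10 lists scored). Within chips the means were 0.15 and 0.10, with the call lost on either chip alone. The non-peptidergic and pruriceptor list (20 members, mean 0.03, adjusted p = 0.79) was not called.

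In the fixed lists of ion channels and of glutamate, GABA and glycine receptors Kcng4 was the 1 called gene, in a potassium channel list of 33 members (mean -0.04, adjusted p = 0.52) in which Kcna1 also passed adjusted over the list alone. Sodium channels (9 members, mean 0.02), calcium channel subunits (12, mean -0.02), TRP, P2X, ASIC, HCN and Piezo channels (21, mean 0.03), glutamate receptors (9, mean -0.04) and GABA and glycine receptors (5, mean -0.11) held 0 called genes, and none of these lists was called. In the axon guidance and adhesion list 1 of 41 members, Ntng1, fell, and the list did not (mean -0.04, adjusted p = 0.46). In the nerve injury list 1 of 11 members, the protease inhibitor Serpinb1a, fell by 0.52, a call lost with the replicate number as a block (adjusted p = 0.052, in a range from 0.0039 to 0.99 over all alternatives). Jun (-0.24) passed adjusted over the list alone, and the list stood at -0.01 (adjusted p = 0.53).

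Glial lists were lower in mutants. The myelinating Schwann cell list had 13 of 16 members below 0 and a mean of -0.17 (camera adjusted p = 0.0015), and adjusted p = 0.43 with an estimated correlation. Mbp (-0.25) and Pmp2 (-0.64), components of myelin, were among the lower members, Mag (0.02) and Pmp22 (0.06) were not, and 0 of 16 passed alone. The list of satellite glia and non-myelinating Schwann cells had 10 of 13 members below 0 and a mean of -0.13 (camera adjusted p = 0.031), and adjusted p = 0.43 with an estimated correlation. S100b (-0.36) was its 1 member lower adjusted over the list alone. Means within chips were -0.18 and -0.16 for the first list and -0.13 and -0.12 for the other, whose call was lost on either chip alone. The call of the satellite glia list was also lost without any 1 of control replicates 3, 4 and 6 and mutant replicates 1, 3, 4 and 5, with adjusted p from 0.051 to 0.097.

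Immune lists were higher. The macrophage and immune list had 16 of 21 members above 0 and a mean of 0.15 (camera adjusted p = 0.0016), and adjusted p = 0.43 with an estimated correlation. The lysozymes Lyz2 (0.56) and Lyz1 (0.52) were higher adjusted over the list alone. The 4 neutrophil genes averaged 0.89 (camera adjusted p = 0.0015), and adjusted p = 0.43 with an estimated correlation. S100a8 (1.42) and S100a9 (1.18), the calprotectin subunits, were higher adjusted over the list alone, and 0 of 4 passed over all probes. Within chips the macrophage means were 0.16 and 0.15 and the neutrophil means 1.21 and 0.57. The neutrophil score was above all control pools in mutant replicates 1, 3 and 5 (1.57, 0.94 and 0.93), while mutant replicates 2, 4 and 6 (-0.41, -0.40 and 0.04) lay within the control range of -1.06 to 0.16. Leaving out control replicate 3 ended the macrophage call (adjusted p = 0.051, in a range from 7.8e-05 to 0.43 over all alternatives).

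**Figure D3:**
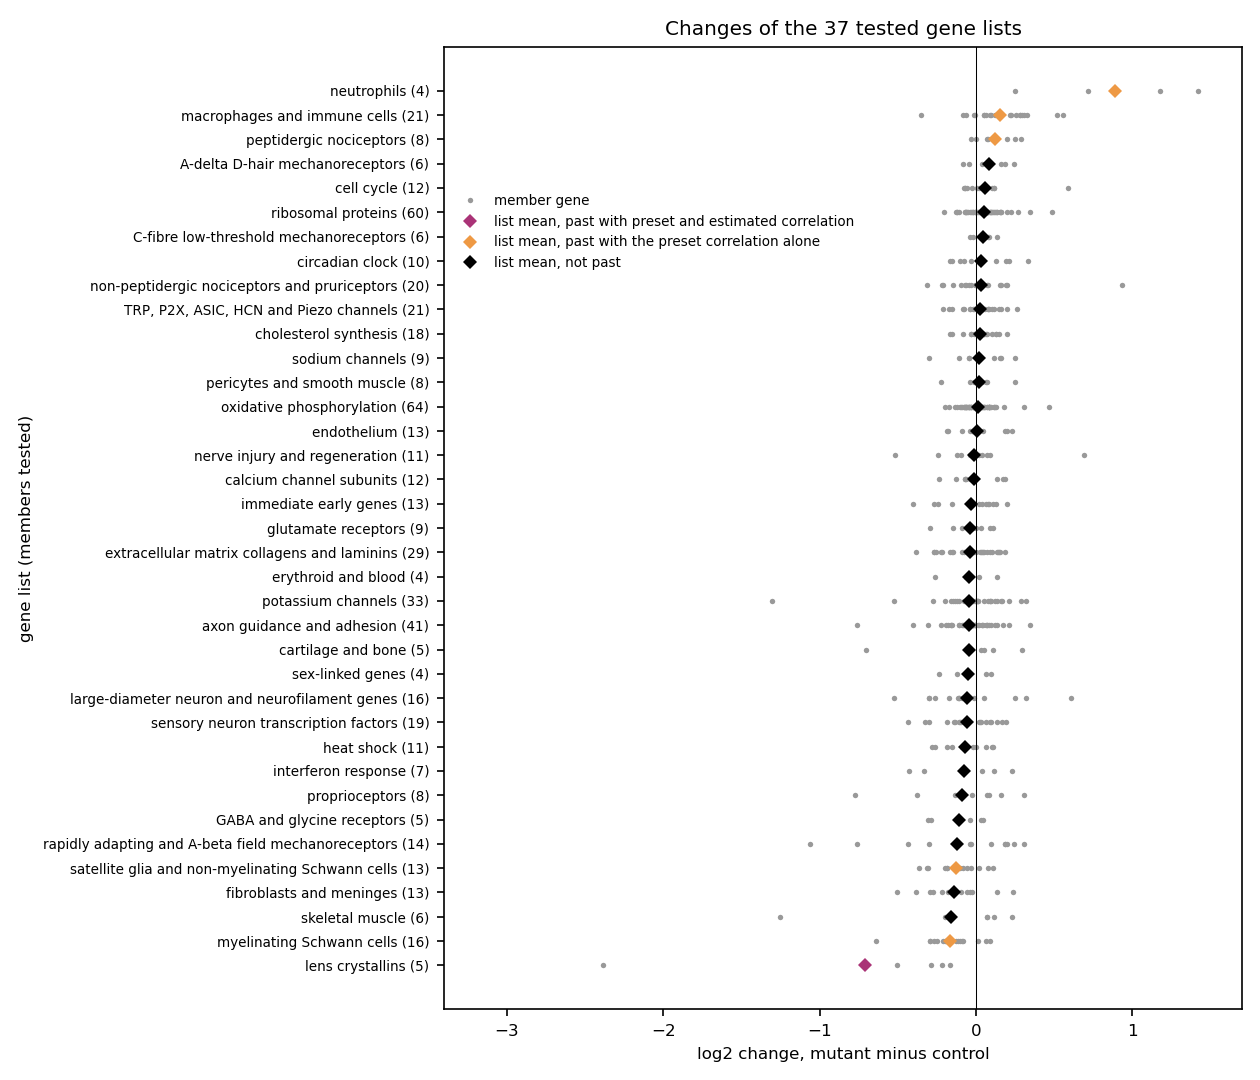
Changes of the 37 tested gene lists. The horizontal axis is the log2 change, mutant minus control; small points are member genes, with their number in parentheses on the vertical axis, and diamonds are list means, coloured by whether the list passed camera at the preset correlation and at the estimated one; 6 lists passed at the preset correlation, with lens crystallins at -0.71 and neutrophils at 0.89 the ends of the range.

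A dissected ganglion also holds other cells, whose lists were tested. Endothelium (13 members, mean 0.01), pericytes and smooth muscle (8, mean 0.02), fibroblasts and meninges (13, mean -0.14, adjusted p = 0.14) and erythroid genes (4, mean -0.04) were not called. The fibroblast and meninges mean was 0.04 within chip 1 (adjusted p = 0.97) and -0.33 within chip 2 (adjusted p = 0.0013). The most abundant detected members were Hba-a1 (0.02), a hemoglobin chain, and Dcn (-0.02), the matrix proteoglycan decorin, with Bgn at 0.03 for cartilage and bone and Lpl at 0.21 for adipocytes. In the skeletal muscle list Myh8 was the 1 of 6 members that fell, while Acta1 (0.07), Actn3 (0.11), Atp2a1 (-0.20) and Eno3 (0.23) did not pass. In the cartilage and bone list Ibsp, bone sialoprotein, was the 1 of 5 that fell by 0.71 (adjusted p = 0.017). Ibsp was detected in 2 of 6 mutant pools, and its size depends on values near background (-0.35 with normexp at offset 50). The Ibsp call was lost without any 1 of control replicate 6 and mutant replicates 2, 3 and 5, with adjusted p from 0.052 to 0.062. The lists of the Maf family, adipocytes and spinal cord cells had 2 detected members each and were not tested as lists.

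The remaining lists were not called: cell cycle (mean 0.06), ribosomal proteins (0.05, adjusted p = 0.093), oxidative phosphorylation (0.01), cholesterol synthesis (0.03), circadian clock (0.03), immediate early genes (-0.03), heat shock (-0.07), interferon response (-0.08), collagens and laminins (-0.04) and sex-linked genes (-0.05). For 9 lists, none of them called, the mean, the median and the direction of the test were not of the same sign: proprioceptors, non-peptidergic nociceptors, immediate early genes, endothelium, skeletal muscle, cartilage and bone, sex-linked genes, oxidative phosphorylation and circadian clock.

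Of the other Maf genes, the small Maf protein gene Mafg stood at -0.06 (adjusted p = 0.94). The 3 Mafa probes were detected on 2 or 3 of the 12 arrays each and were not tested. Next to Maf in chromosome order, Wwox stood at 0.17 (adjusted p = 0.90) and Dynlrb2 was detected on 1 array. Next to Isl1, Pelo stood at 0.06 (adjusted p = 0.94) and Parp8 has no named probe here.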

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

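All tests of explanations in this part were chosen after the results were seen, apart from the count over other splits of the arrays. Of 82 groups of 6 values looked at (named genes and list scores), 6 had 1 pool far from the other 5, where chance gives about 1 in 20 groups, or 4 here. All 6 were in control pools. Control 6 was the highest for Kcng4 (6.45, next 6.12) and Rgs6 (7.04, next 6.68) and the lowest for Mag (8.36, next 8.89). Control 5 was the lowest for Calb2 (9.13, next 9.76) and the highest for Hba-a1 (12.22, next 11.71). Control 2 was the highest for Pelo (9.90, next 9.77). None of these pools overlapped the mutant pools for Kcng4, Rgs6 or Calb2.

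From the 462 splits of the 12 arrays into 6 and 6, 100 were drawn with the real one included. Of these, 2 gave at least as many genes as the 25 of the real split, which is under the 0.05 level. The rest were not drawn, so this share is itself an estimate. Since 1 other split gave more genes, a source of the count apart from genotype is not excluded. The highest of the other splits gave 30 genes, 0 of them among the 25. That split put 5 arrays of chip 2 on 1 side, but the split exactly by chip gave 0 genes, and 23 genes passed with the chip as a block. Of the 30 genes, 7 lay on chromosome 8. The median of the other splits was 0 genes.

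The immune lists were higher and the glial lists lower in mutants, which a change in the cellular makeup of the ganglia could produce. When pools rather than genes were permuted, 0 of these 4 lists passed over the 10 lists scored (lowest adjusted p = 0.114). The unadjusted exact permutation p was 0.045 for neutrophils and for myelinating Schwann cells, 0.043 for satellite glia and 0.093 for macrophages. The crystallin list passed (adjusted p = 0.022) and the peptidergic nociceptor list did not (adjusted p = 0.126). Members that vary together between pools whatever the genotype may thus account for the 4 calls. Blood left in the ganglia would raise erythroid and neutrophil genes alike. Their scores differed by 0.93 (exact permutation p = 0.0628), which over all pools does not decide. Hba-a1 changed by 0.02 with a 95% interval from -0.35 to 0.39. In mutant replicates 1, 3 and 5, with the highest neutrophil scores (1.57, 0.94 and 0.93), erythroid scores were -0.35, 0.01 and -0.08. In the same pools Hba-a1 stood at 11.08, 12.14 and 11.91, against 11.51 to 12.22 in control pools. Mutant replicate 1 thus lay below all control pools for Hba-a1, while mutant replicates 3 and 5 lay above all of them but control 5. These values do not decide whether blood was the source of the neutrophil rise. Fewer glial cells would raise endothelial and macrophage genes alike, and the difference of those scores was 0.14 (exact permutation p = 0.273), which leaves it open. An effect of the genotype on these cells also stays open.

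Mutant replicate 3 stood apart: it lay at 30.7 on the first principal component, where the other arrays ran from -14.6 to 11.4, and its mean correlation with the others was the lowest at 0.980. In this pool genes of the integrated stress response were high, among them Chac1 (12.04 against a mean of 9.54 in the other 11 pools, 5.66-fold), Nupr1 (2.91-fold), Mthfd2 (2.96-fold) and Slc7a5 (2.87-fold). In a list of targets of the transcription factor ATF4, leaving out the 6 genes seen first, all 18 tested members were above the mean of the other mutant pools, by 0.56 on average, above all 10000 random lists matched on level. The array also had the fewest detected probes, 12822, yet a dimmer array alone would not move 1 list to percentile 100 of the random lists. That test shows that ATF4 targets were high in this pool and not why. What raised them was not tested, since the design names no difference for 1 pool. Without this pool 21 genes passed, all among the 25.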

How the results depend on the processing

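The Eif2s3y level as a covariate, the list test without a list's called members and the focus on mutant replicate 3 were chosen after the data were seen. The direction of all 25 genes was kept in every alternative that tested them, and the count stayed between 18 and 31 apart from single chips. For single chips and for arrays left out, the kept direction follows from the separation of the pools. Strict detection on all arrays left 18 genes and 20 probes, since Maf and 6 others were then untested. The genes higher in mutants, 2 in the reported fit, became 1 with normexp at offset 50, with no background correction, with the processed table, with no filter, with strict detection and with array weights, and 4 with a trended robust prior; the cause was not tested. Within chip 1 there were 4 genes (4 lower, 0 higher; 4 probes) and within chip 2 there was 1 (1 lower, 0 higher; 1 probe), from 6 arrays each. Leaving out each array gave 18 to 29 genes, 1 to 3 higher, 17 to 28 lower, 21 to 36 probes, a Maf change of -2.93 to -2.78, 3 to 7 lists and 0 to 1 probes for genotype by chip (1 without mutant replicate 1). Without control replicate 3 there were 3 lists. Maf ranged from -3.42 to -1.82 over all settings, its adjusted p from 2.1e-10 to 0.011.

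With the replicate number as a block 18 genes passed, 17 of them among the 25, and 7 lists. Deviations of same-numbered pools correlated by -0.12 to 0.19, and 2 of 6 numbers correlated best with their own, which does not settle whether the numbers pair the pools. The 8 genes that lost their calls with this block were Serpinb1a, Vstm2b, Ngef, Omg, Glb1l2, Cpne6, H4c12 and Sphk1, with adjusted p from 0.052 to 0.26. Without each list's called members 6 lists passed. Of the 6 called lists lens crystallins alone held a called member, so for the others nothing was removed. Estimated correlation and fry left 1 list each, lens crystallins. Oxidative phosphorylation, not called at 0.01, was higher within chip 1 (0.0884, adjusted p = 0.041) and lower within chip 2 (-0.06, adjusted p = 0.0095); the cause was not tested. Further lists not called over all arrays passed on 1 chip alone. Within chip 1 these were ribosomal proteins (0.15, adjusted p = 1.6e-05), axon guidance and adhesion (-0.13, adjusted p = 0.0082), sensory neuron transcription factors (-0.15, adjusted p = 0.037) and large-diameter neuron genes (-0.15, adjusted p = 0.047), whose means on chip 2 were -0.05, 0.04, 0.03 and 0.04. Within chip 2 it was fibroblasts and meninges (-0.33, adjusted p = 0.0013), at 0.04 on chip 1. The fibroblast list also passed with the replicate block (adjusted p = 0.048) and without mutant replicate 2 (adjusted p = 0.020). The ribosomal list passed without control replicate 1, 4 or 5 or mutant replicate 6, with adjusted p from 0.00081 to 0.036. Wnt7a passed with the replicate block and the trended prior, Caln1 with the trended prior and Apobec1 without mutant replicate 5. Of values not past the threshold in either fit, 20 for named genes (6 genes) and 59 for lists changed sign. Named genes lost a call in 48 of their alternative fits, 16 for Ngef and 6 for Ibsp. Signal over background limits Maf, Kcng4 and Ngef, whose dim groups were undetected, and Crybb1, Crybb3 and Ibsp, detected in 1, 2 and 2 mutant pools. Sizes depend on the background step: with normexp at offset 50 those of Maf (-1.82), Kcng4 (-0.70), Hapln1 (-0.88), Slc35d3 (-0.46), Rgs6 (-0.44), Ibsp (-0.35) and Ngef (0.42) were smaller by over 1.5 times, and of these Ngef lost its call.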

Other observations

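The tests of explanations in this part were chosen after the results were seen. Some transcripts of the sex chromosomes split the pools. The Y-linked gene Eif2s3y stood between 8.86 and 9.38 in controls 1, 2 and 6 and in mutants 1, 4 and 5, and between 4.41 and 4.63 in the remaining 6 pools, in which Xist, the transcript of the inactive X chromosome, was between 7.55 and 8.53. In the first 6 pools Xist stood between 5.48 and 6.05. Each group thus held 3 pools of either kind, and with the Eif2s3y level as a covariate 23 genes passed, all 23 among the 25. Kdm5d, also Y-linked, split the pools as Eif2s3y did (5.94 to 6.56 against 4.50 to 4.80). The dim Y-linked gene Uty did not (5.77 to 6.46 against 5.63 to 6.10).

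Some genes split the pools across both genotypes. On chromosome 15, Gramd4 stood between 4.54 and 4.73 in replicates 5 and 6 of both groups and between 6.89 and 8.21 in the other 8 pools. Atf4 (7.33 to 7.51 against 9.08 to 10.64), Tomm22 (7.48 to 7.66 against 8.99 to 9.94) and Mgat3 (7.18 to 7.55 against 7.87 to 8.90) of the same chromosome split the pools alike, and Tspo did so in the opposite direction (9.02 to 9.14 against 8.02 to 8.85). Emb, the tested gene next to Isl1 on chromosome 13, stood at 5.08 and undetected in control 6, and between 11.55 and 12.86 in the other 11 pools. A candidate explanation is segments of the mixed strain background that differ between pools. Among the 500 genes that varied most within groups, outside chromosomes 8, 15, X and Y but with the chromosome of Emb, pairs 20 to 60 tested genes apart had a mean squared correlation of 0.217, above all 1000 shuffled gene orders (median 0.169, highest 0.186). Pairs closer than 20 genes reached 0.290, and pairs 100 to 200 genes apart 0.175, within the shuffled range. A strain variant under a probe and a true difference in transcript level were not separated here.

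The same background bears on Kcng4 and Vat1l (-0.26, adjusted p = 0.28), which lie near Maf. Of the 25 called genes 3 lie on chromosome 8: Maf, Kcng4 and Calb2. Calb2 lies farther from Maf than the genes counted next, and linked strain differences were not tested for it. With Kcng4 and Vat1l left out, 6 of the 40 tested genes nearest to Maf had an unadjusted p under 0.05. Windows of that size along the genome had a median of 2 and a 95th percentile of 6. The count near Maf was 7 with Kcng4 and Vat1l kept. Strain differences linked to the targeted locus, or an effect of Maf on these genes, may each account for the Kcng4 loss. The count of 6, at the edge of the range, leaves both open. Among 27 tested genes near Isl1 there were 0.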
